A study of Mus musculus with 16 samples.

How the data were processed

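The series measured RNA in aortic valves of mice on the C57BL/6J background in 4 groups. Control mice (CON), mice carrying human renin and angiotensinogen transgenes as a hypertension model (HT), ApoE knockout mice as a hypercholesterolaemia model (HC) and mice with both (HC/HT) were planned as 4 mice each. Per the labels, total RNA was taken with Trizol, cleaned on RNeasy columns and treated with DNase. Nugen Ovation RNA-Seq v2 amplified cDNA from 1 ng of RNA, and libraries were made with the KAPA hyper prep kit. The submitters' processing notes name FastQC 0.11.2, Bowtie 1.0.1, SAMtools 0.1.9 and edgeR without a version, with reads placed on mm10. The normalisation step itself is not given in the sources used here.

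The deposited values are a score, the authors' normalised counts rounded to whole numbers, in 1 table of 20992 genes. The 15 deposited totals lie between 10207900 and 10210300, so they do not carry the sequencing depth of each library. The depth is unknown, and no counting interval or limit of detection is given. Of 16 planned libraries 15 were used: 4 CON, 4 HT, 4 HC and 3 HC/HT. 1 column of values has no name in its header and was not used. Of the names, 17944 matched a current mouse symbol, 842 an older symbol, and 2206 had no match. Positions are those of mm10.

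All values were multiplied by 1 common factor, 0.0979537, which sets the median library total to 1000000, and are given in these units here. A value near 0.2 or less is a deposited 1 or 2, so low means carry little precision. Genes with at least 1 unit in at least 4 libraries were tested, 15004 in all. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with trend and robust) on log2 of the value plus a pseudocount of 1. The 15 libraries were in 1 fit with group and sex as terms, since the groups hold unequal numbers of females. The 6 comparisons were HC with CON, HT with CON, HC/HT with each of the other groups, and the interaction of HC and HT. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided, over the 15004 genes of that comparison. Log2 differences carry their standard error (SE), and levels are the mean ± SD over the mice of a group. The pseudocount makes the fitted differences of low genes smaller than the ratio of their means.

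A set of 34 gene lists was tested with limma camera at a preset correlation of 0.01, for lists with at least 5 members tested, adjusted over the lists of a comparison. The list p given below is this adjusted value. The lists cover immune cells (macrophage, T and NK cell, B and plasma cell, neutrophil and mast cell) and immune functions (MHC class II and antigen presentation, complement, chemokine and cytokine, interferon stimulated). They cover matrix (fibrillar collagen and crosslinking, basement membrane and elastic fibre, proteoglycan and hyaluronan, matricellular and wound response), TGF-beta and BMP signalling, and Notch and Wnt signalling. Valve and vessel lists are myofibroblast and smooth muscle contractile, osteogenic and chondrogenic, valve interstitial and fibroblast, endothelial, and endothelial activation and adhesion. Metabolic and hormonal lists are cholesterol biosynthesis and uptake, lipid handling and LXR targets, renin-angiotensin system, oxidative stress, and mitochondrial respiratory chain. The others are platelet, proliferation, cardiomyocyte, adipocyte, erythroid and blood, melanocyte, nerve and Schwann cell, immediate early and handling response, unfolded protein response, and cytosolic ribosomal protein. Lists share some members, for example the C1q genes in macrophage and complement. The same lists were tested with an estimated correlation and with fry. Fry asks whether a list moves one way, not whether it moves against other genes.

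Genes are named by a rule. In each comparison it takes up to 10 genes per direction with the largest differences among those that passed with groups that do not overlap, without predicted or unnamed genes. Where fewer than 10 passed, it takes the 10 smallest p. It adds up to 4 members of each called list and any list member that passed, and always Apoe, Ren1, Agt, Col1a1, Col3a1, Tgfb1, Postn, Fn1, Spp1, Runx2, Acta2, Cd68 and Vcam1. The rule was written for 4 against 4 libraries and was applied to those at hand. The lists, this rule, the model, the tests and the alternatives, except those named as added, were fixed before the data were examined. Apoe was compared between the knockout and the other libraries by an exact permutation test, two-sided, and Xist and Y-linked genes were set beside the labelled sex.

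The alternatives planned were quantile normalisation, median-of-ratios factors, pseudocounts of 0.25 and 4, no filter, a filter at 5, no sex term, a replicate block, limma array weights, eBayes without trend and robust, an adjusted p under 0.1, only the groups compared, females alone (3 HC and 2 HC/HT), and leaving out each library in turn. A scaling without the 4 most abundant rows and a fit without the 3 libraries that correlate least with the others were added after seeing the data. Tests on read counts were not run, since the values are not raw counts. The fits and the list test were tried on simulated data with 200 changed genes among 15004. Changed genes were drawn from those with a mean log2 value above 3, and every gene varied independently of the others. The varying share of the most abundant rows was not simulated. The rates below therefore do not cover low genes, and the list check does not cover lists whose members vary together. At an 8-fold change it called between 93.9% and 98.5% of changed genes over the 6 comparisons, and at a 2-fold change between 1.49% and 17.9%. Unchanged genes made up between 6.32% and 11.3% of the calls, and 0 calls had the wrong sign. A simulated changed list had an adjusted p of 3.87e-31, and 1 other of the 34 lists was called. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.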

Results

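The table covers aortic valves of 15 mice: 4 CON, 4 HT, 4 HC and 3 HC/HT. Hypertension and hypercholesterolaemia both accompany thickening and stiffening of the valve, and the 4 groups allow each to be seen alone and together. Each library listed between 16006 and 17608 genes above 0. The sex that Xist and the Y-linked genes show matched the label in 15 of 15 mice, with Xist at 2321 units or more in females and at 16.8 or less in males. CON held 1 female and 3 males, HT 2 and 2, HC 3 and 1, and HC/HT 2 and 1. CON replicate 2 was the only CON female, HC replicate 2 the only HC male and HC/HT replicate 1 the only HC/HT male. Leaving out 1 of these leaves a group of 1 sex, whose comparison then leans on the sex term. Calls lost by these omissions need not mark the mouse as an outlier. In every library 4 rows, RN45S (a ribosomal RNA precursor), AK018753, GU332589 and AK140265, took between 32.4% and 62.7% of the total. Their share was 41.6 ± 11.2% in CON (mean ± SD, n = 4), 54.4 ± 9.63% in HT (n = 4), 41.4 ± 8.86% in HC (n = 4) and 50.9 ± 4.87% in HC/HT (n = 3). Because all libraries were deposited with equal totals, a larger share of these rows lowers every other gene's value. Median-of-ratios factors, which correct for this, ranged from 0.636 to 1.34. The median Spearman correlation of a library with the others lay between 0.890 and 0.934, lowest in HC/HT replicate 2 (0.890), HT replicate 3 (0.893) and HT replicate 2 (0.895).

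**Figure D1:**
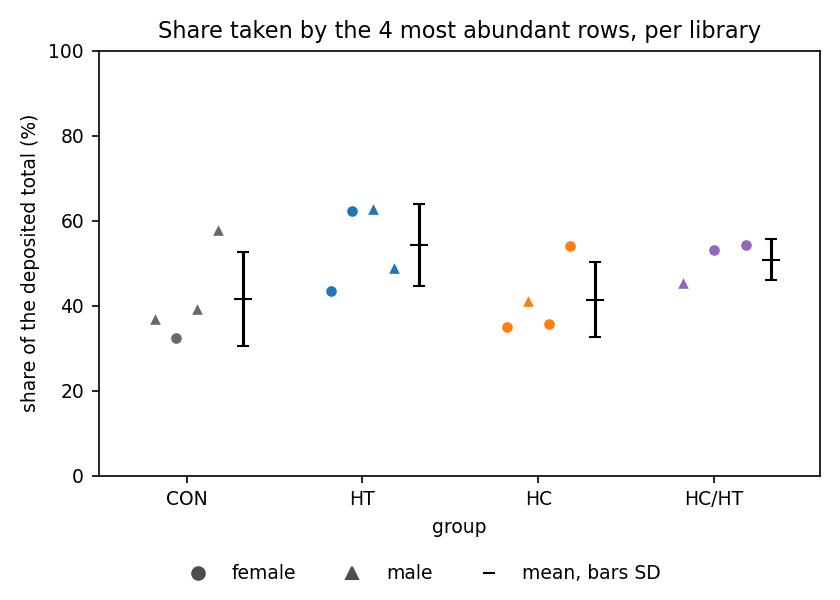
Share of each library's deposited total taken by the 4 most abundant rows (y axis, percent) in the 4 groups (x axis); circles are females, triangles males, and the dash with bars is mean and SD. Shares run from 32.4% to 57.8% in CON and from 43.5% to 62.7% in HT, so these groups overlap.

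Apoe, the lipoprotein ligand removed in the knockout, stood at 761 ± 305 units in CON, 342 ± 227 in HT, 6.86 in HC (from 2.15 to 12.3) and 7.77 ± 1.92 in HC/HT. All 7 knockout libraries (up to 12.3 units) lay below all 8 others (56.6 to 1014 units). The log2 difference was -5.81, with an exact permutation two-sided p of 0.000311, the smallest that 6435 splits can give. It stayed between -6.22 and -5.59 when each library was left out. HT replicate 3 was the lowest of the other libraries, at 56.6 units. A further 8 transcripts were near 0 in both knockout groups and passed the test in HC against CON and in HC/HT against CON. The most abundant was AK041157, an unannotated transcript, at 52.9 ± 17.4 units in CON, 35.4 ± 32.8 in HT, 0.759 ± 0.793 in HC and 0.914 ± 0.735 in HC/HT. The others were AK039360, AK048672, DQ687153, DQ540451, AK029949, Gm3893 and 4930578G10Rik, the last listed at 0 in all 7 knockout libraries. In HC against CON, AK029949 passed in only 6 of 20 alternatives (largest adjusted p 0.39), and DQ540451 in 18, not without CON replicate 2 or HC replicate 2. Only Gm3893 and 4930578G10Rik have a position, on mm10 chromosome 4 from 42091207 to 42092287 and from 42735545 to 42846248. The naming rule leaves both out, and they are named here after their values were seen. The human transgenes have no row, nor has mouse Ren1. Agt was under 2 units in every library, with an exact permutation p of 1. Ace, which makes angiotensin II, stood at 180 ± 39.0 units in the knockout and 149 ± 77.0 in the other libraries (exact permutation p 0.218).

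**Figure D2:**
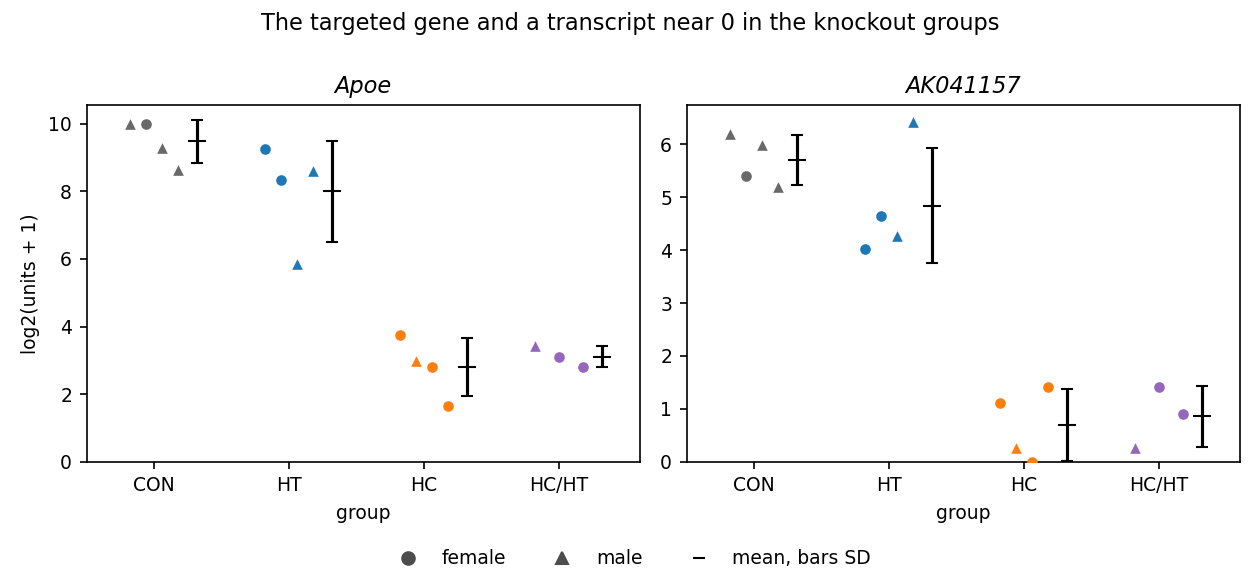
Level of Apoe (left) and of the transcript AK041157 (right) in each library, as log2 of the value in units plus 1 (y axis), by group (x axis); circles are females, triangles males, and the dash with bars is mean and SD. All 7 knockout libraries lie below all 8 others for Apoe.

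In HC valves, 16 genes were higher than in control valves, some of them from the macrophage and lipid handling lists. Cd5l, a macrophage survival factor, rose from 1.18 ± 0.831 units in CON (n = 4) to 38.3 ± 13.9 in HC (n = 4), a log2 difference of 4.25 ± 0.44 (SE) with adjusted p 1.72e-06. Gpnmb, a lysosomal glycoprotein of foam cells, rose from 49.2 ± 23.4 to 439 ± 208 units (3.13 ± 0.46, adjusted p 0.00222). The cholesterol exporter Abcg1 rose from 10.1 ± 4.56 to 73.1 ± 17.7 units (2.72 ± 0.38, adjusted p 3e-04). Spp1, which encodes osteopontin, stood at 8.11 ± 10.5 units in CON and 847 ± 868 in HC (6.19 ± 0.99, adjusted p 0.045). Of the 15004 genes, 16 passed as higher and 9 as lower in HC, with a median difference of all genes of -0.02, and in all 25 the 4 HC libraries did not overlap the 4 CON libraries. Such separation was seen in 686 genes, 4.57% of those tested, where chance gives 2.86%. In the limma fit, however, 602 genes had an unadjusted p under 0.05, fewer than the 750.2 that chance gives.

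Atp6v0d2, a subunit of the lysosomal proton pump, rose from 3.53 ± 1.99 to 90.1 ± 37.0 units (4.05 ± 0.57, adjusted p 0.00216), and Acp5, a lysosomal acid phosphatase, from 1.20 ± 0.680 to 17.5 ± 5.90. Mmp12, the macrophage elastase, rose from 27.0 ± 5.39 to 270 ± 124 units, and the lipid receptor Trem2 from 5.36 ± 2.93 to 34.0 ± 7.03. Lgals3 (3.20, adjusted p 0.043), the interleukin 1 antagonist Il1rn (2.99, adjusted p 0.0397) and the sheddase Adam8 (2.53, adjusted p 0.0063) rose too. Abca1, a second cholesterol exporter, rose from 75.7 ± 19.0 to 263 ± 73.6 units (1.73 ± 0.34, adjusted p 0.0169). Tenascin C, Tnc, rose from 7.25 ± 4.91 to 37.0 ± 11.6 units (2.14 ± 0.45, adjusted p 0.0334). Abca1 (from 53030787) and Tnc (from 63959785) lie on chromosome 4, between 40 and 70 Mb, as do the near-0 transcripts Gm3893 and 4930578G10Rik. Of the macrophage list, 3 of 34 members passed over all genes tested and 18 passed adjusted over the list alone, all higher, with a list median of 1.29 and list p 1.34e-35, against adjusted p = 0.193 with an estimated correlation. Cd68 was at 33.9 ± 8.26 in CON and 121 ± 34.0 units in HC, which did not pass (adjusted p 0.145). Of the lipid handling and LXR target list, 3 of 27 members were higher and 1, Apoe, lower over all genes, and 11 higher and 1 lower adjusted over the list alone (list p 1.46e-13, median 0.80, against adjusted p = 0.193 with an estimated correlation).

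Inflammatory lists were higher in HC and muscle lists lower. Of 29 chemokine and cytokine genes 26 had positive differences, 0 passed over all genes and 7 adjusted over the list alone, with Cxcl1 at 2.08 (adjusted p 0.189) and Ccl9 at 1.38 (adjusted p 0.338). Its list p was 3.98e-13, against adjusted p = 0.193 with an estimated correlation. In the T and NK cell list 19 of 20 members were positive and 4 passed adjusted over the list alone, among them Il7r, whose difference was 2.17 (list p 5.25e-12, against adjusted p = 0.193 with an estimated correlation). CON replicate 4 stood at the level of the HC libraries in this list (mean log2 level 0.50, HC from 0.37 to 1.06). All 18 MHC class II and antigen presentation genes were positive (list p 5.38e-07, median 0.63), as were 15 of 19 complement genes (list p 2.84e-05, median 0.55), 22 of 27 oxidative stress genes (list p 1.83e-05, median 0.45) and 26 of 29 proliferation genes (list p 7.4e-07, median 0.48). The matricellular list (list p 6.33e-08, median 0.40, with 2 members past over all genes and 3 adjusted over the list alone), the immediate early list (8.12e-06, median 0.45) and the endothelial activation list (0.00281, median 0.51) were also higher. With an estimated correlation the complement list had adjusted p = 0.514 and the others of these adjusted p = 0.485. All 22 myofibroblast and smooth muscle contractile genes had negative differences, with a median of -1.14 (list p 9.4e-14, against adjusted p = 0.284 with an estimated correlation). The regulatory myosin light chain Myl9 stood at 147 ± 68.9 units in CON and 27.5 ± 27.5 in HC, but 0 of the 22 passed over all genes or adjusted over the list alone. The libraries overlapped in the mean log2 level of this list, with CON replicate 4 at -0.67 inside the HC range (-1.13 to 0.77) and CON replicates 1 and 3 highest, at 1.92 and 1.99. Cardiomyocyte genes were lower in 27 of 28 members (list p 8.9e-07, median -0.91) and adipocyte genes in 9 of 13 (0.0426, median -0.49), both with adjusted p = 0.611 with an estimated correlation. The adipocyte call was kept in only 8 of 23 alternatives and lost with quantile normalisation and median-of-ratios factors. Cholesterol biosynthesis (0.0114, median 0.39) and the unfolded protein response (0.0242, median 0.23) were higher, each with adjusted p = 0.923 with an estimated correlation. Single libraries ended some of these calls. They were cholesterol biosynthesis without CON replicate 4 (0.0606), the unfolded protein response without CON replicate 4, HC replicate 2 or HC replicate 3 (up to 0.454) and complement without CON replicate 2 or HC replicate 2 (up to 0.296). Immediate early genes were lost without HC replicate 4 (0.105), and adipocyte genes without CON replicate 1 or 3 or HC replicate 1 or 3 (up to 0.153).

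Main matrix genes did not pass in HC against CON. Col1a1 stood at 400 ± 73.8 units in CON and 450 ± 192 in HC (0.14 ± 0.37), and Col3a1 at 450 ± 138 and 1148 ± 751 (1.07 ± 0.50, adjusted p 1). Fn1 (0.86), Postn (-0.47), Tgfb1 (-0.09), Runx2 (0.53), Vcam1 (0.84) and Acta2 (-1.23) did not pass. The count of 25 became 9 without CON replicate 2 and 13 without HC replicate 2, and 31 without HC replicate 1. Cd5l, Abcg1, Apoe, AK041157, AK039360 and AK048672 passed in 21 of 21 alternatives, whereas Spp1 passed in 10 of 21 (largest adjusted p 0.332), Il1rn in 8 (0.405), Lgals3 in 13 (0.527), Tnc in 14 (0.506) and Abca1 in 16 (0.284). Leaving out HC replicate 2 or HC replicate 3 ended each of these 5 calls. Spp1, Il1rn and Lgals3 each kept their call in only 1 of 8 single-library omissions. Abca1 also lost its call without CON replicate 2, and Tnc without CON replicate 1 or 4. Gpnmb, Acp5, Adam8, Atp6v0d2, Mmp12 and Trem2 also lost their call without CON replicate 2, with a largest adjusted p over the alternatives from 0.0536 for Gpnmb to 0.165 for Trem2.

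**Figure D3:**
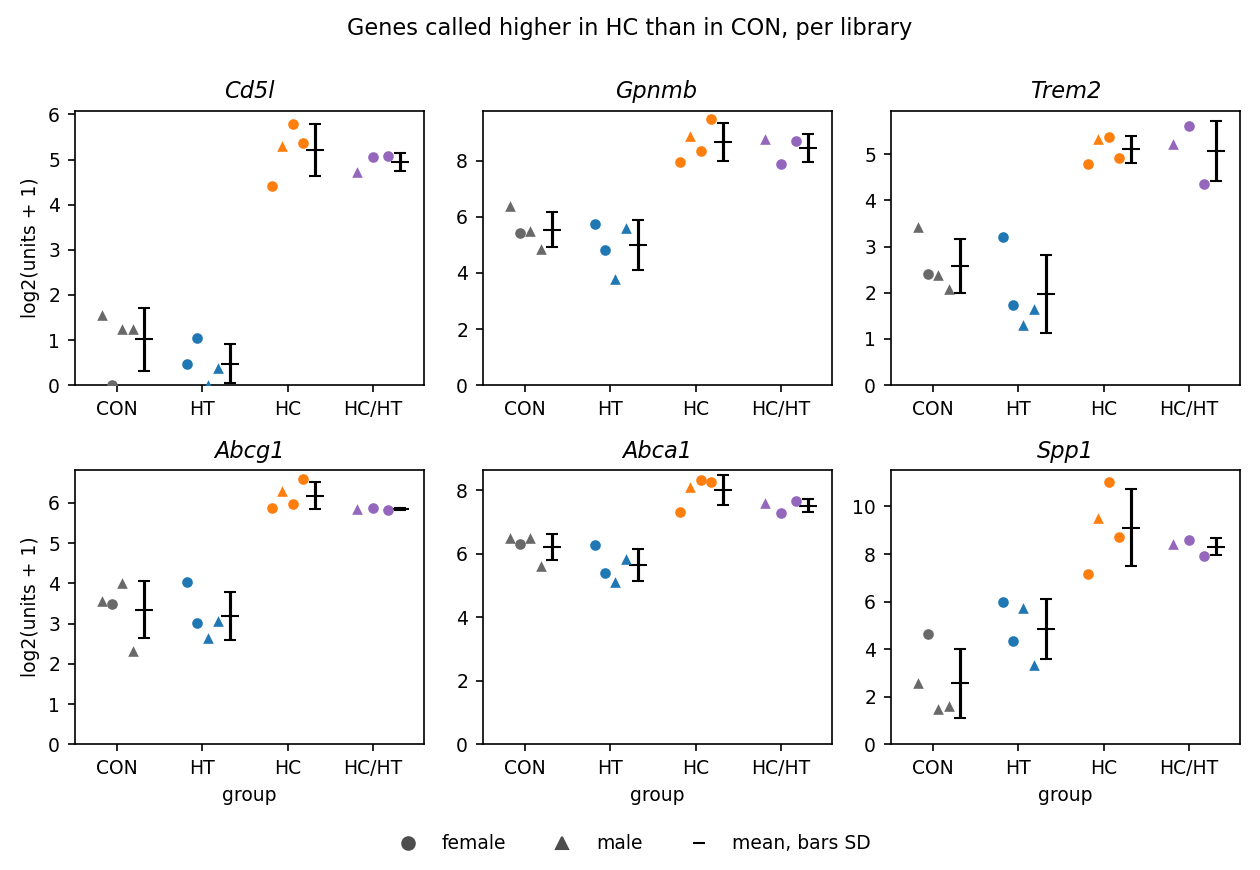
Levels of Cd5l, Gpnmb, Trem2, Abcg1, Abca1 and Spp1 in each library, as log2 of the value in units plus 1 (y axis), by group (x axis); circles are females, triangles males, and the dash with bars is mean and SD. Cd5l means are 1.18 and 0.441 units in CON and HT and 38.3 and 30.1 in HC and HC/HT.

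In HT valves no gene passed against CON. The smallest adjusted p was 0.18, for the aldehyde dehydrogenase Aldh3a1, at 8.79 ± 1.94 units in CON (n = 4) and 1.35 ± 0.521 in HT (n = 4), a log2 difference of -2.11 ± 0.40 (SE). Clec14a, an endothelial lectin, stood at 36.9 ± 10.1 in CON and 13.7 ± 6.56 units in HT (adjusted p 0.262), and Sdpr, a caveolar protein, at 153 ± 21.8 and 65.7 ± 21.6 (adjusted p 0.351). Gpr182, Gria4, Necab1, Stra6, Megf10, Smtnl2 and Zfp36l1 followed, with differences from -1.41 (Zfp36l1) to -2.04 (Necab1). Limma called 0 genes, while 1922 had an unadjusted p under 0.05, against 750.2 by chance. The median difference of all genes was -0.42, so most genes were lower in HT on this scale. With median-of-ratios factors the median was -0.01 and the count at an unadjusted p under 0.05 was 739, and with quantile normalisation they were 0.00 and 767, so the general lowering depends on the scaling. The 3 other ways of calling that gave more than 0 genes were limma array weights (3 higher, 1619 lower), a fit of only the groups compared (4 higher, 204 lower) and a replicate block (0 higher, 1 lower).

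Ribosomal, oxidative stress, macrophage and blood genes formed the lists lower in HT. All 45 cytosolic ribosomal protein genes were lower, with a median of -1.01, or -0.54 with median-of-ratios factors. 0 passed over all genes and 3 adjusted over the list alone, with Rpl10a at -1.15 and Rpl5 at -1.14 (list p 1.38e-08). All 27 oxidative stress genes were lower, among them catalase (Cat) at -1.01 (list p 0.00398), and 32 of 34 macrophage genes, among them Lyz2 at -1.48 and Mrc1 at -1.51 (list p 0.00194). All 8 erythroid and blood genes were lower (list p 0.000244), and the globin Hbb-bs stood at 1051 ± 1702 units in CON and 85.9 ± 92.4 in HT. The cholesterol biosynthesis and uptake list was higher in 17 of 23 members (list p 6.95e-11, median 0.35, or 0.81 with median-of-ratios factors). Each of these 5 lists had adjusted p = 0.96 with an estimated correlation. The macrophage call was lost without CON replicate 4 (0.1) and without HT replicate 3, where the list p was 0.917 with the direction turned, and the list turned higher without the 3 libraries that correlate least (0.0081). The erythroid call was lost without CON replicate 4 or HT replicate 4 (up to 0.446), and the oxidative stress call without HT replicate 3 or 4 (up to 0.105).

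In HT 3 more lists passed as higher although their medians were negative. Cardiomyocyte genes had list p 2.88e-05 with a median of -0.16 and a mean of -0.08, chemokine and cytokine genes 0.00953 with -0.40 and -0.19, and matricellular genes 0.0371 with -0.18 and -0.19, a call kept in 11 of 23 alternatives. With median-of-ratios factors the medians were 0.27, 0.07 and 0.23, and none of the 3 lists passed. All 3 had adjusted p = 0.96 with an estimated correlation. The atrial peptide Nppa stood at 52.2 ± 76.4 units in CON and 515 ± 959 in HT, and titin (Ttn) at 688 ± 516 and 1739 ± 2655. HT replicate 2 held the highest HT value in 26 of the 28 cardiomyocyte genes, and without it the list lay lower in HT, with list p 0.0457, while without CON replicate 2 it was 0.965. The chemokine call was lost without CON replicate 2 or HT replicate 1 (up to 0.641), and the matricellular call without CON replicate 3 or 4 or HT replicate 1 or 3 (up to 0.507). Matrix genes did not pass in HT against CON, with Col1a1 at -0.29, Col3a1 at -0.56, Postn at -0.61, Fn1 at -0.16 and Tgfb1 at -0.70. Runx2 (-0.14), Vcam1 (0.29), Acta2 (-0.26), Cd68 (-0.95), Apoe (-1.59) and Spp1 (2.11 ± 0.94, adjusted p 0.388) did not pass either.

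In HC/HT valves several macrophage genes called in HC stood high again, and Lyve1 and contractile genes stood low. Lyve1, a hyaluronan receptor of lymphatic endothelium and some resident macrophages, fell from 40.2 ± 11.0 units in CON (n = 4) to 1.04 ± 0.688 in HC/HT (n = 3), a log2 difference of -4.50 ± 0.61 (SE) with adjusted p 0.00129. Cd5l rose to 30.1 ± 4.13 units (3.98 ± 0.46, adjusted p 1.47e-05), and Gpnmb to 362 ± 109 (2.92 ± 0.49, adjusted p 0.00837). Mylk, the myosin light chain kinase, fell from 104 ± 35.7 to 13.5 ± 2.71 units (-2.59 ± 0.53, adjusted p 0.0416). Of the 15004 genes, 22 were higher and 48 lower, with log2 differences from 1.75 to 3.98 and from -1.62 to -6.57. Groups did not overlap in 68 of the 70. Such separation was seen in 1583 genes, 10.6% of those tested, where chance gives 5.71%.

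Other genes that rose were Atp6v0d2 (3.24), the growth factor Pdgfb (3.09, from 5.29 ± 1.61 to 52.1 ± 45.9 units), the neutrophil attractant Cxcl1 (2.69), Acp5 (2.47), Trem2 (2.43), Abcg1 (2.40), the tight junction gene Cldn1 (2.29) and the integrin Itgae (2.28). Those that fell included Fibin (-2.75), the cardiac transcription factor Tbx5 (-2.74, from 18.7 ± 11.9 to 1.99 ± 0.878 units), the sarcomere gene Tcap (-2.58) and the Wnt receptor Fzd2 (-2.13). Contractile genes were negative in 22 of 22 members with a median of -2.04. 1 passed over all genes and 7 adjusted over the list alone (list p 5.73e-14, against adjusted p = 0.47 with an estimated correlation). Myl9 stood at 5.19 ± 2.34 units in HC/HT and did not pass (-4.27, adjusted p 0.0644). Cholesterol biosynthesis and uptake genes were positive in 22 of 23 members, with a median of 1.37, 0 past over all genes and 9 adjusted over the list alone (list p 4.77e-19, against adjusted p = 0.447 with an estimated correlation). In the macrophage list 2 of 34 passed over all genes and 5 higher and 1 lower adjusted over the list alone (list p 2.53e-17, median 1.04), and in the lipid handling list 2 were higher and 1 lower, or 6 and 1 adjusted over the list alone (1.87e-07, median 0.61). The T and NK cell list (4.35e-06, median 0.55) was higher as well, and all 3 had adjusted p = 0.47 with an estimated correlation. The chemokine list was higher (1.36e-09, median 0.78, against adjusted p = 0.447 with an estimated correlation), with 1 member past over all genes and 2 adjusted over the list alone.

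Smaller list differences in HC/HT against CON covered interferon stimulated genes (list p 0.00016, median 0.26) and matricellular genes (0.0069, median 0.26), both higher, with adjusted p = 0.699 with an estimated correlation. The interferon induced Oas2 stood at 11.4 ± 5.15 units in CON and 38.6 ± 8.92 in HC/HT (adjusted p 0.0857), and Spp1 at 321 ± 74.2 in HC/HT (adjusted p 0.0586). MHC class II (0.000805), endothelial activation (0.0069, although its member Lyve1 fell), proliferation (0.000139), melanocyte (0.000805) and immediate early genes (0.000613) were higher. Cardiomyocyte (1.01e-07, median -2.04), proteoglycan and hyaluronan (0.0021, median -0.60), adipocyte (0.00861) and erythroid genes (0.00236) were lower. Each of these 9 lists had adjusted p = 0.58 with an estimated correlation. Calls were lost without CON replicate 2 for interferon stimulated (0.283), MHC class II (0.0596) and melanocyte genes (0.0523), and without CON replicate 4 for erythroid genes (0.33). Those of matricellular genes were lost without HC/HT replicate 1 or 2 (up to 0.121), and of immediate early genes without HC/HT replicate 1 (0.0571). Among proteoglycans, chondroadherin (Chad) had a difference of -2.94 and osteoglycin (Ogn) of -2.92, neither past the test. Col1a1 (-0.40), Col3a1 (0.05), Postn (-0.76), Fn1 (0.15), Tgfb1 (-0.26), Runx2 (0.65), Vcam1 (0.88), Cd68 (1.41) and Acta2 (-2.26) did not pass.

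The split of calls in HC/HT against CON moved with scaling, from 31.4% higher to 54.1% with median-of-ratios factors (60 higher, 51 lower) and 55.7% with quantile normalisation (59 higher, 47 lower), where the median of all genes on the scale used here was -0.20. The count of 70 became 7 without CON replicate 2, 30 without CON replicate 1, 24 without CON replicate 3, 12 without HC/HT replicate 1, 14 without HC/HT replicate 2 and 143 without HC/HT replicate 3. CON replicate 2 was the only CON female and HC/HT replicate 1 the only HC/HT male, so the fits without them lean on the sex term. Cd5l, Apoe, AK041157, AK039360 and AK048672 passed in 20 of 20 alternatives, Lyve1 in 19 (adjusted p 0.0501 without HC/HT replicate 1, the largest of the 20) and Mylk in 7, with none of the 7 single-mouse omissions keeping Mylk past the threshold. Cldn1 also passed in only 7 of 20, Pdgfb and Itgae in 9, Fibin and Fzd2 in 10, Atp6v0d2 and Tbx5 in 13, Cxcl1 in 14, Trem2 and Acp5 in 15, Gpnmb in 18, Abcg1 in 19, and Tcap in 9 of 19. Trem2 and Acp5 were lost without CON replicate 2, HC/HT replicate 1 or HC/HT replicate 2 (largest adjusted p 0.203 and 0.211).

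**Figure D4:**
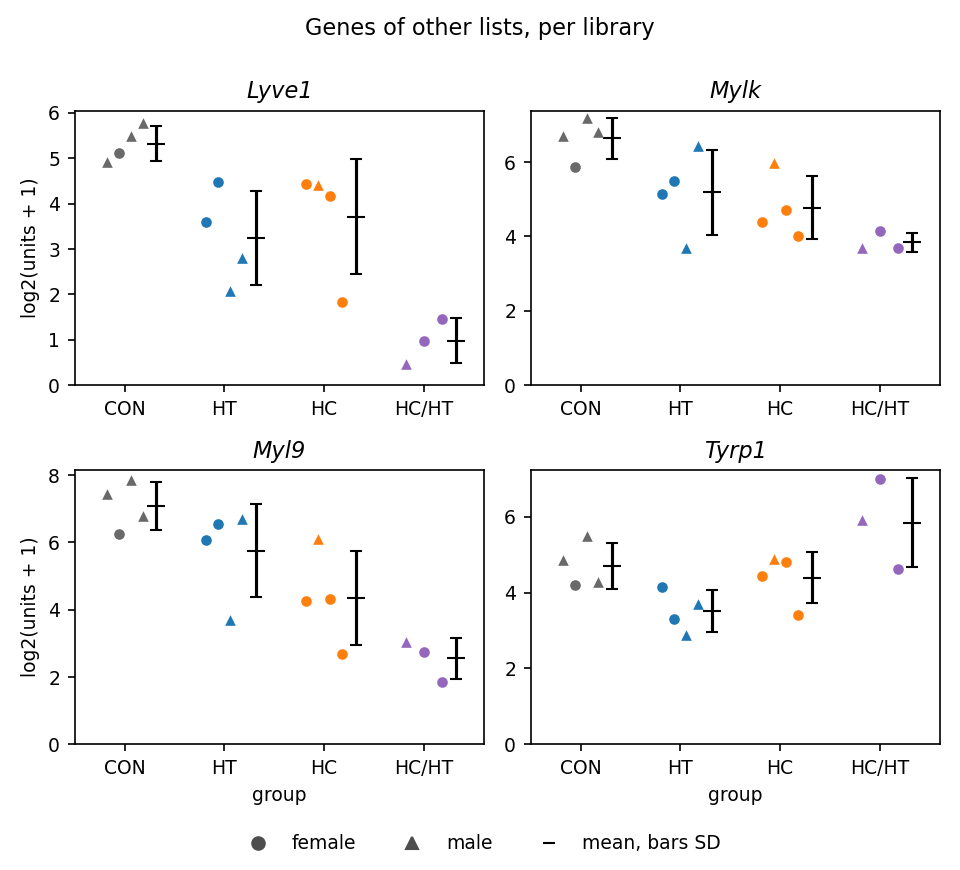
Levels of Lyve1, Mylk, Myl9 and Tyrp1 in each library, as log2 of the value in units plus 1 (y axis), by group (x axis); circles are females, triangles males, and the dash with bars is mean and SD. Lyve1 means are 40.2 units in CON and 1.04 in HC/HT.

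Between HC/HT and HC, the comparison that adds hypertension to hypercholesterolaemia, no gene passed. Trhde, which degrades thyrotropin-releasing hormone, had the smallest adjusted p (0.152), at 11.5 ± 4.11 units in HC (n = 4) and 1.44 ± 0.926 in HC/HT (n = 3), a log2 difference of -2.37 ± 0.44 (SE). Lyve1 stood at 15.2 ± 8.57 in HC and 1.04 ± 0.688 units in HC/HT (-2.71 ± 0.58, adjusted p 0.62). The prolactin receptor Prlr (-2.03), Sncg (-2.02), Vwc2 (-1.88), Pcdh18 (-1.78), Pcp4l1 (-1.77) and the lymphatic growth factor Figf (-1.43) had negative differences, and Moxd1 and Ano3 positive ones (both 1.85). Limma called 0 genes, with 661 at an unadjusted p under 0.05 against 750.2 by chance and a median of all genes of -0.18. A replicate block called 1 gene, array weights 2, and median-of-ratios factors 0 (838 at an unadjusted p under 0.05). Without HC/HT replicate 3 the count was 3 and without HC replicate 4 it was 2, and females alone (2 HC/HT, 3 HC) gave 0 (631 at an unadjusted p under 0.05).

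Cholesterol biosynthesis and uptake was the list with the smallest p in this comparison (list p 1.68e-22, against adjusted p = 0.605 with an estimated correlation), with 22 of 23 members higher in HC/HT and a median of 1.00. Hmgcs1 (1.45) and Sc4mol (1.36) were among the 4 members with the smallest p, and 0 members passed over all genes or adjusted over the list alone. Interferon stimulated (0.00145, median 0.15) and melanocyte genes (0.000136, median 0.37) were higher too. Matrix and interstitial cell lists were lower: proteoglycans (0.00666, median -0.54, with Podn at -1.85 and Acan at -1.33), fibrillar collagens (0.0384, median -0.34, kept in 13 of 23 alternatives, with Col11a1 at -1.42 and Col6a2 at -0.99) and valve interstitial genes (0.0312, median -0.49). The contractile (0.00555, median -0.91) and cardiomyocyte lists (0.0289, median -0.93) were lower, and 45 of 45 ribosomal protein genes (0.00307, median -0.52). Complement (0.0312), oxidative stress (0.0312), mitochondrial respiratory chain (0.0312), unfolded protein response (0.0308) and erythroid genes (6.31e-06, with Hbb-bs at -3.07) were lower. All lists of this paragraph after the first had adjusted p = 0.941 with an estimated correlation. Without HC replicate 2 the number of lists called was 4 instead of 14, and the cardiomyocyte (0.807), mitochondrial (0.823) and ribosomal (0.823) lists turned upward, while without HC/HT replicate 3 the number was 6 and the mitochondrial (0.26) and ribosomal (0.386) lists turned. Without HC replicate 3 the number was 8, and the complement, collagen, valve interstitial, oxidative stress, unfolded protein and mitochondrial calls were lost. Leaving out HC replicate 2 also ended the calls of complement, collagens, proteoglycans, contractile, valve interstitial, oxidative stress and unfolded protein genes, and leaving out HC/HT replicate 3 all of these but the contractile one. Their largest adjusted p over single omissions were, in that order, 0.823, 0.457, 0.353, 0.686, 0.452, 0.804 and 0.452. The interferon call was lost without HC/HT replicate 2 (0.0577). Col1a1 (-0.54), Col3a1 (-1.02), Postn (-0.29), Fn1 (-0.71), Tgfb1 (-0.17), Runx2 (0.12), Vcam1 (0.04), Spp1 (-0.74), Cd68 (-0.31), Apoe (0.35) and Acta2 (-1.03) did not pass.

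Between HC/HT and HT, the comparison that adds hypercholesterolaemia to hypertension, macrophage and lipid genes were higher in HC/HT. Cd5l rose from 0.441 ± 0.456 units in HT (n = 4) to 30.1 ± 4.13 in HC/HT (n = 3), a log2 difference of 4.49 ± 0.45 (SE) with adjusted p 9.07e-07. Gpnmb rose from 35.2 ± 18.6 to 362 ± 109 units (3.46 ± 0.47, adjusted p 0.00121), Trem2 from 3.55 ± 3.14 to 34.6 ± 14.3 (3.06 ± 0.45, adjusted p 0.000751) and Abcg1 from 8.79 ± 4.49 to 56.6 ± 1.13 (2.62 ± 0.39, adjusted p 0.000751). Cd68, a general macrophage marker, rose from 21.1 ± 16.4 to 94.2 ± 15.5 units (2.37 ± 0.42, adjusted p 0.0125), and lysozyme 2 (Lyz2) from 311 ± 311 to 1453 ± 286. In all, 48 genes were higher and 8 lower, and groups did not overlap in any of the 56. Such separation was seen in 926 genes, 6.17% of those tested, where chance gives 5.71%.

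The macrophage list had 6 of 34 members past the test over all genes and 28 adjusted over the list alone, all higher (list p 4.94e-30, median 1.65). The lipid handling list had 5 higher and Apoe lower, or 12 and 1 adjusted over the list alone, with the lipid droplet gene Plin2 at 1.95, Abca1 at 1.85 and the lysosomal lipase Lipa at 1.53 (list p 5.76e-11, median 1.07). In the melanocyte list 3 of 11 members passed over all genes and 6 adjusted over the list alone (5e-07, median 1.23). The pigment enzyme Tyrp1 rose from 11.0 ± 4.53 to 69.5 ± 51.5 units (2.37, adjusted p 0.0343), Pmel from 4.41 ± 2.01 to 22.0 ± 10.0 (2.08) and the receptor Kit from 4.33 ± 2.19 to 18.5 ± 8.11 (1.87). T and NK cell genes were higher in 20 of 20 members, with Tcra past over all genes at 2.04 and 4 adjusted over the list alone (4.47e-08). The contractile list was negative in 20 of 22 members (7.68e-22, median -1.51) and the cardiomyocyte list in 28 of 28 (1.09e-22, median -1.56). All 6 lists had adjusted p = 0.258 with an estimated correlation. Lgals3 (2.92), in no list, rose, as did, among list members, Cxcl1 (2.52), Clec7a (2.33), Cd22 (2.21), Laptm5 (2.13), Itgb2 (2.05) and cathepsin D, Ctsd (1.76). The collagen gene Col11a1 fell from 5.09 ± 3.06 to 0.555 ± 0.463 units (-1.94 ± 0.44, adjusted p 0.0472), a call kept in 8 of 19 alternatives and in 0 of 7 single-library omissions (largest adjusted p 0.562).

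Further lists higher in HC/HT against HT were MHC class II (2.64e-07, median 0.99, against adjusted p = 0.452 with an estimated correlation), chemokine (4.24e-06, median 1.05, against adjusted p = 0.324 with an estimated correlation) and complement (0.00314, median 0.86, against adjusted p = 0.719 with an estimated correlation). Cholesterol biosynthesis was higher in 23 of 23 members (4.06e-07, median 0.98) and oxidative stress in 23 of 27 (0.000101, median 0.62). Proteoglycans passed as lower (5.32e-05) with 13 members positive and 13 negative, a median of -0.01 and a mean of -0.35, and adipocyte genes as lower (0.0103, median -0.38). These 4 had adjusted p = 0.499 with an estimated correlation. Immediate early genes were higher (0.000439, median 0.61, against adjusted p = 0.567 with an estimated correlation), as were proliferation (0.00992, against adjusted p = 0.803 with an estimated correlation), interferon stimulated (0.00788, against adjusted p = 0.852 with an estimated correlation) and ribosomal protein genes (0.00655, against adjusted p = 0.913 with an estimated correlation). Col1a1 (-0.11), Col3a1 (0.62), Postn (-0.15), Fn1 (0.31), Tgfb1 (0.44), Runx2 (0.80), Vcam1 (0.59), Acta2 (-2.01) and Spp1 (3.34, adjusted p 0.308) did not pass. The interferon call was lost without HT replicate 2 or 3 or HC/HT replicate 2 (up to 0.362) and turned to lower without the 3 libraries that correlate least (0.00308). The ribosomal call was lost without HT replicate 3 or 4 or HC/HT replicate 2, and without HC/HT replicate 1 the list turned (0.899). Also lost were proliferation without HT replicate 2 or 4 or HC/HT replicate 2 (up to 0.27), complement without HT replicate 3 or HC/HT replicate 2 (up to 0.158) and adipocyte genes without HT replicate 2 (0.485). The calls were 85.7% higher here, where the median of all genes was 0.21, and 67.6% higher with median-of-ratios factors (25 higher, 12 lower). With no filter 4 were higher and 4 lower, and without the 3 libraries that correlate least 2 were higher and 4 lower. The count of 56 became 7 without HT replicate 2, 7 without HC/HT replicate 1, 10 without HC/HT replicate 2, 24 without HT replicate 3, 23 without HT replicate 4, 259 without HT replicate 1 and 6 without the 3 libraries that correlate least. Cd5l, Gpnmb and AK041157 passed in 20 of 20 alternatives. Of the others named here as risen, Clec7a and Cd22 passed in 6 of 20, Cxcl1 in 7, Laptm5, Itgb2 and Ctsd in 8, Lyz2, Lgals3 and Kit in 9, Tyrp1 and Lipa in 10, Plin2 in 12, Pmel in 13, Abca1 in 16, and Tcra in 9 of 19. Cd68 passed in 15 of 20, not without HT replicate 2, HC/HT replicate 1 or HC/HT replicate 2 (largest adjusted p 1).

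The interaction asks whether the effect of both conditions departs from the sum of the single effects, and no gene passed. Tyrp1 had the highest interaction value of the 10 genes with the smallest p that the rule names, at 26.8 ± 12.3 units in CON, 11.0 ± 4.53 in HT, 21.5 ± 8.57 in HC and 69.5 ± 51.5 in HC/HT (2.58 ± 0.67 on the log2 scale, adjusted p 1). Aggrecan (Acan) was at 1.30 ± 0.694 in CON, 4.33 ± 2.15 in HT, 5.12 ± 2.89 in HC and 1.18 ± 0.596 units in HC/HT (-2.51 ± 0.68), and Tnc, at 37.0 ± 11.6 in HC and 12.3 ± 1.45 units in HC/HT, had -1.97 ± 0.62. Further named genes were AK169509 (2.46), Samd1 (2.07), AK044689 (1.87), Moxd1 (1.83), Smtnl2 (1.76), Prss23 (-2.35) and AK011482 (-2.07). Limma called 0 genes, with 207 at an unadjusted p under 0.05 against 750.2 by chance, and each alternative run called 0 as well. On simulated data, where genes varied independently, a 4-fold interaction was found in 38.8% of the changed genes, none of them low. Of the lists 7 passed, 2 of them positive. Melanocyte genes were positive in 11 of 11 members (8.87e-07, median 1.02, with 0 past over all genes and 2 adjusted over the list alone) and cholesterol biosynthesis genes in 21 of 23 (0.00497, median 0.79). Negative were cardiomyocyte (5.91e-09, median -0.63), matricellular (0.000566, median -0.14) and contractile genes (0.00317, median -0.48). Fibrillar collagens (0.00497) and proteoglycans (0.00497) passed as negative with medians of 0.04 and 0.10 and means of -0.07 and -0.18, and with median-of-ratios factors the medians were -0.23 and -0.17. All 7 had adjusted p = 0.936 with an estimated correlation. Single libraries ended the calls of contractile (without CON replicate 2 or 4, HT replicate 2 or HC replicate 2, up to 0.667) and cardiomyocyte genes (without CON replicate 2, HT replicate 2 or HC replicate 2, up to 0.247). Without HT replicate 1, HC replicate 2 or HC/HT replicate 3 those of collagens (up to 0.131) and proteoglycans (up to 0.252) ended, and without HC/HT replicate 3 that of matricellular genes (0.472). The cholesterol call ended without CON replicate 2, HC replicate 2, HC/HT replicate 1 or HC/HT replicate 2, and without HT replicate 4 the list turned (0.959). Interaction values of Spp1 (-2.86 ± 1.37), Apoe (1.95), Col1a1 (-0.25), Col3a1 (-0.45), Postn (0.32), Fn1 (-0.55), Tgfb1 (0.53), Runx2 (0.26), Acta2 (-0.78), Cd68 (0.65) and Vcam1 (-0.25) did not pass.

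Knockout mice were compared with mice without the knockout, once without and once with the transgenes, and called genes were shared. HC against CON and HC/HT against HT share no library, and 9 genes were higher in both: Abca1, Abcg1, Acp5, Atp6v0d2, Cd5l, Galnt6, Gpnmb, Lgals3 and Trem2, where independent lists would share 0.0512. A further 7 were lower in both, where 0.0048 would be shared. They are Apoe and some of the transcripts near 0 in both knockout groups, which may not be separate agreements. Among the shared higher genes, Abca1 lies on chromosome 4 between 40 and 70 Mb, as do Gm3893 and 4930578G10Rik. For Abca1 a strain difference there cannot be told apart from an effect of the knockout. Independent lists are a loose yardstick here, since both comparisons come from 1 fit with the same variance and sex terms. Across the 15004 genes, which are not independent replicates, the differences had r = 0.568, inside the range of 100 draws of unchanged groups (mean -0.02, from -0.77 to 0.65). HC against CON and HC/HT against CON, which share the CON libraries, had 9 genes higher and 9 lower in both, where independent lists would share 0.0235 and 0.0288. Their r was 0.714, inside the range that unchanged groups give with the same CON libraries (mean 0.451, from -0.32 to 0.88). HC against CON and HT against CON shared 0 genes and had r = 0.325, inside the range that unchanged groups give with the same CON libraries (mean 0.511, from -0.25 to 0.90). With the CON libraries split into separate sets for the comparisons the correlation averaged -0.04, from -0.126 to 0.0848. Of the 34 lists 10 passed in none of the 6 comparisons. Their smallest list p were 0.0544 for B and plasma cell, 0.0982 for osteogenic and chondrogenic, 0.103 for platelet, 0.108 for renin-angiotensin system and 0.123 for endothelial. They were 0.125 for Notch and Wnt signalling, 0.14 for TGF-beta and BMP signalling, 0.141 for neutrophil and mast cell, 0.205 for basement membrane and elastic fibre and 0.475 for nerve and Schwann cell genes.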

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

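The splits of the libraries and the test of a chromosome 4 segment on genes not called were chosen before their results were seen, and the other tests here only after. For the 16 genes called higher in HC than in CON, among them Trem2, Mmp12, Gpnmb, Abca1 and Abcg1 of the macrophage and lipid handling lists, several technical explanations were set against the ApoE knockout, the biological difference the design names. Scaling by library totals is argued against as the whole cause, since 14 of the 16 passed with median-of-ratios factors too. Sex is argued against as the whole cause, since in HC/HT against HT, whose libraries enter the HC and CON comparison only through the variance and sex terms of the common fit, their median difference was 2.14 within females (2 HC/HT, 2 HT) and 2.90 within males (1 HC/HT, 2 HT). The male value rests on 1 HC/HT mouse, so it carries no spread between HC/HT mice. More macrophages of an unchanged profile cannot be told apart from a changed macrophage state. In HC/HT against HT the 16 genes had a median 0.90 above that of 31 other macrophage list members (95% bootstrap interval 0.0653 to 1.49). The interval takes genes as its units, so it leaves out the spread between mice. The 16 are also the strongest genes of the pattern, and a higher baseline of the others would damp their rise. If the label numbers give an order of processing, which the labels do not say, that order cannot be told apart from the knockout, since they run up to 7 in the knockout groups and from 9 in the others, with 0 knockout libraries inside the range of the others.

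For the 8 transcripts near 0 in both knockout groups besides Apoe, a candidate explanation is a strain difference on chromosome 4 carried with the knockout line. Only 2 of the 8 have a position, and both lie within 5 Mb of each other, which 0.00561 of 100000 random draws also showed. The draws took unrelated genes, and neighbouring copies of 1 sequence would lie close together too. This share therefore does not set a strain difference above shared reads. Reads shared between copies of 1 sequence are another candidate explanation, with a median SD of pairwise log2 ratios of 0.281 over the CON and HT libraries against a median of 0.678 (5th percentile 0.526) in random sets, but transcripts regulated together would show this too and no sequence was examined, while a segment around the targeted gene is argued against for the 2 with a position, 0 of which lie within 20 Mb of Apoe. Between 40 and 70 Mb on chromosome 4, 4 of the 16 genes called higher in HC (Abca1, Tnc, 1300002K09Rik and AI427809, the last 2 named after their values were seen) lie among 169 genes tested (Fisher's exact p 3.43e-05, in a window chosen after these positions were seen). Of 163 genes there that were not called, 0 moved in both knockout comparisons (median 1.88% in 244 other windows, with 0.0% of them lower), which met the bound written beforehand against a segment that also changes the 4 called genes, but leaving out the called genes made that bound wrong, so it cannot be told apart from an effect of the knockout on Abca1 (1.73 in HC against CON, 1.85 in HC/HT against HT), 1300002K09Rik (2.82 and 1.59) and AI427809 (2.38 and 1.29), while Tnc (2.14 and 0.17) was not raised in both, which a segment carried by both knockout groups would need.

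Cardiomyocyte genes passed as higher in HT than in CON only against the other genes, since the median and mean of the list were negative on the scale used here. With median-of-ratios factors the list did not pass. For this call, heart muscle carried over in 1 library is a candidate explanation. Without HT replicate 2 the list was no longer higher but lower, with adjusted p 0.0457 (over all alternatives from 6.78e-23 to 0.965). Leaving out CON replicate 2 also ended the call (adjusted p 0.965). That mouse was the only CON female, so the fit without it leans on the sex term. It therefore cannot tell whether the call rests on HT replicate 2 alone. The bound for this test was worded for the upward call after its value was seen. HT replicate 2 had the highest HT value in 26 of the 28 members tested, but it was singled out for its level of these genes, and a joint regulation in 1 mouse would give this too, so cell content cannot be told apart from gene regulation. The list was fixed before the data were examined, and an effect of the transgenes on these genes stays open and untested.

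Other splits of the same libraries show what chance can give. In HC against CON 25 genes were called and at most 2 in the other splits, 1 of 35 being as large, and in HC/HT against CON 70 and at most 9, again 1 of 35. This argues against chance for both gene counts taken whole but cannot exclude it, since 1 of 35 is the smallest share these splits can give. Both counts include 9 lower genes that are Apoe, removed by design, and the transcripts near 0 in both knockout groups. Those 9 alone exceed the 2 and equal the 9 of the other splits. The genes called higher were not split apart from them, so for these the splits decide nothing. Splits that mix knockout and CON libraries also put any knockout difference into the spread, which lowers their counts. For the 56 genes of HC/HT against HT chance is neither excluded nor argued against. Here 3 of 35 splits were as large, counting the real one and the largest, which gave 310. Splits with several times the real calls point to a structure of the samples, and in the next 2 comparisons the split with the most calls parts the libraries by the share of the 4 most abundant rows. In HT against CON the real split gave 0 genes with limma (1922 at an unadjusted p under 0.05), so all 35 were as large, and the split that put CON replicates 1, 2 and 3 with HT replicate 1, shares of 32.4% to 43.5% against 49.0% to 62.7%, gave 3054. In HC/HT against HC the real split also gave 0 (661 at an unadjusted p under 0.05, 35 of 35 as large), and HC replicate 4 with HC/HT replicates 2 and 3, shares of 54.1%, 53.0% and 54.3%, against the rest gave 247. For the interaction the real count was 0 (207 at an unadjusted p under 0.05), 100 of 100 splits drawn were as large, and the highest was 18. For the lists chance cannot be excluded in any of the 6 comparisons. In HC against CON 15 of 35 splits gave 16 or more (highest 20), in HT against CON 34 gave 8 or more (highest 22) and in HC/HT against CON 9 gave 17 or more (highest 26). In HC/HT against HC 9 gave 14 or more (highest 19), in HC/HT against HT 12 gave 17 or more (highest 22), and for the interaction 95 of 100 gave 7 or more (highest 26).

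Single libraries stood far from the other 3 of their group in 15 of 231 group values tested, where chance gives about 1 in 20, or 11.55. In mean log2 level of a list, HC replicate 4 was low for valve interstitial genes (-0.39, others 0.47 to 0.58), cholesterol biosynthesis (-0.45, others -0.05 to -0.02), renin-angiotensin system (-0.18, others 0.39 to 0.49), adipocyte (-0.23, others 0.22 to 0.27) and mitochondrial genes (-0.62, others 0.58 to 0.80). CON replicate 4 was high for T and NK cell genes (0.50, others -0.52 to -0.38) and low for the unfolded protein response (-0.71, others 0.37 to 0.43), and HC replicate 1 was high for endothelial genes (0.39, others -0.08 to -0.02). Of single genes, in units, Acta2 was at 42.5 in HT replicate 3 (others 299 to 375), Adam8 at 1.08 in HT replicate 2 (others 6.56 to 8.03), and Cldn1 at 0 in HT replicate 3 (others 3.62 to 4.90). DQ540451 was at 7.05 in HT replicate 4 (others 1.86 to 1.96), Lyve1 at 2.55 in HC replicate 4 (others 17.0 to 20.7), and AK039360 and DQ687153 each at 0.196 in HC replicate 1, a deposited value of 2, with the others at 0.

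Differences between the effect of hypertension with and without hypercholesterolaemia, tested as the interaction, passed for 7 lists. The medians were 0.0397 for fibrillar collagens, 0.10 for proteoglycans, -0.14 for matricellular, -0.48 for contractile, 0.79 for cholesterol biosynthesis, -0.63 for cardiomyocyte and 1.02 for melanocyte genes. Fibrillar collagens and proteoglycans passed as negative although these medians are positive. Of 100 splits drawn, 95 gave 7 or more lists. All 7 had adjusted p = 0.936 with an estimated correlation.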

How the results depend on the processing

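The fits with a scaling without the 4 most abundant rows and without the 3 libraries that correlate least were chosen after seeing the data, and the other alternatives before. Over 1415 values of 70 calls of named genes, 1015 kept direction and threshold, 400 lost the threshold and 0 turned. Over 1825 values of 79 list calls, 1508 kept both, 302 lost the threshold and 15 turned. The cause was not tested for any of the changes below, except that fewer libraries or groups leave fewer residual degrees of freedom. Leaving out CON replicate 2, HC replicate 2 or HC/HT replicate 1 also leaves a group of 1 sex in a fit with a sex term. The labels do not say whether the numbers in the titles pair the mice, and the residual correlations do not settle it, so the block below is only an alternative. Of 21 same-number pairs 10 correlated above 0.1 (range -0.25 to 0.49), with a mean of 0.093 against -0.030 for other pairs. Of 15 libraries 6 correlated best with their own number. Tests on read counts with edgeR and DESeq2 were not run, since the values are not raw counts. The unknown depth limits what can be said of genes at a few units.

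Counts of genes called moved over 1.5 times as follows. For HC against CON (25) they were 41 with no sex term, 42 with a replicate block, 260 with limma array weights and 48 with only the groups compared. For HT against CON (0) they were 1 with a replicate block, 1622 with array weights and 208 with only the groups compared. For HC/HT against CON (70) they were 132 at an adjusted p under 0.1, 106 with quantile normalisation, 111 with median-of-ratios factors, 19 with no filter, 26 with a filter at 5, 222 with a replicate block, 976 with array weights, 23 without the 3 libraries and 151 with only the groups compared. For HC/HT against HC (0) they were 1 with a replicate block and 2 with array weights. For HC/HT against HT (56) they were 93 at an adjusted p under 0.1, 37 with median-of-ratios factors, 36 with a pseudocount of 0.25, 8 with no filter, 138 with a replicate block, 27 with eBayes without trend and robust, 6 without the 3 libraries and 221 with only the groups compared.

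Lists called were 0 with an estimated correlation and 0 with fry in each of the 6 comparisons. They were 14 in HT against CON without the 3 libraries (8 as reported), 7 in HC/HT against HC with eBayes without trend and robust (14), and for the interaction (7) 11 with array weights, 13 with a replicate block and 14 without the 3 libraries. The correlation of HC and HT differences from CON (0.325) ran from -0.126 to 0.0848 over the 6 ways to split the CON libraries into separate sets, negative in all but the highest, and was 0.267 with no sex term.

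Leaving out each library in turn gave 9 (without CON replicate 2) to 31 genes in HC against CON, 0 to 0 in HT against CON, 7 (without CON replicate 2) to 143 (without HC/HT replicate 3) in HC/HT against CON, 0 to 3 (without HC/HT replicate 3) in HC/HT against HC, 7 (without HT replicate 2 or HC/HT replicate 1) to 259 (without HT replicate 1) in HC/HT against HT and 0 to 0 for the interaction. In the same order lists ran from 14 to 19, 7 to 18, 15 to 22, 4 to 17, 14 to 20 and 5 to 12, and the Apoe difference from -6.22 to -5.59.

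List directions turned in these cases, given with the adjusted p. In HT against CON they were macrophage (0.0081 without the 3 libraries, 0.917 without HT replicate 3), cardiomyocyte (0.0081 without the 3 libraries, 0.0457 without HT replicate 2, 0.937 with fry), chemokine (0.561 with fry) and matricellular genes (0.554 with fry). In HC/HT against HC they were cardiomyocyte (0.807), mitochondrial (0.823) and ribosomal genes (0.823) without HC replicate 2, and mitochondrial (0.26) and ribosomal genes (0.386) without HC/HT replicate 3. In HC/HT against HT they were interferon stimulated (0.00308 without the 3 libraries) and ribosomal genes (0.899 without HC/HT replicate 1), and for the interaction cholesterol biosynthesis (0.959 without HT replicate 4). Over all libraries left out, the adjusted p of these lists ran in HT against CON from 1.54e-12 to 0.917 (macrophage) and from 6.78e-23 to 0.965 (cardiomyocyte, highest without CON replicate 2). In HC/HT against HC it ran from 2.38e-08 to 0.814 (cardiomyocyte), 5.25e-05 to 0.823 (mitochondrial) and 5.00e-09 to 0.823 (ribosomal), in HC/HT against HT from 2.33e-08 to 0.899 (ribosomal), and for the interaction from 6.99e-11 to 0.959 (cholesterol biosynthesis).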

Other observations

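Further genes that the naming rule takes are given here in units, as mean ± SD, and none of the 6 passed in any of the 6 comparisons. The smooth muscle gene Synpo2 stood at 109 ± 65.7 in CON (n = 4), 53.4 ± 18.5 in HT (n = 4), 41.4 ± 22.4 in HC (n = 4) and 19.7 ± 13.7 in HC/HT (n = 3). Myocd, a driver of smooth muscle genes, stood at 10.9 ± 9.94 in CON, 6.46 ± 3.01 in HT, 2.42 ± 3.15 in HC and 0.620 ± 0.371 in HC/HT. The vasoconstrictor peptide gene Edn1 stood at 7.35 ± 2.58 in CON, 27.6 ± 35.7 in HT, 9.80 ± 1.97 in HC and 46.7 ± 47.6 in HC/HT. The adhesion gene Selp stood at 33.7 ± 8.84 in CON, 25.6 ± 2.78 in HT, 87.3 ± 40.1 in HC and 71.9 ± 32.9 in HC/HT. Of the fat cell genes, Thrsp stood at 4.41 ± 2.29 in CON, 1.71 ± 1.04 in HT, 4.73 ± 3.09 in HC and 0.620 ± 0.574 in HC/HT, and Cidec at 1.71 ± 1.47 in CON, 0.931 ± 0.965 in HT and 0.122 ± 0.245 in HC, and was listed at 0 in all 3 HC/HT libraries.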
